A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

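RNA was measured in roots of rice seedlings grown in hydroponic culture, per the labels, and taken at 14 days. The wild type ZH11 and 2 lines overexpressing OsTCP19, called TG1 and TG2, gave 3 libraries each, 9 in all, and the series design text calls the repeats of each line biologically independent. Poly(A) RNA was sequenced on the BGISEQ-500 platform. The authors deposited a single table of FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) with 1 column per library, per the file headers. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.1.0, Bowtie2 2.2.5 and RSEM 1.2.8, with no role or order for any of them. The genome build and the annotation are not given in the sources used here.

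The deposited table holds 44987 entries, of which 43855 carry LOC_Os locus IDs, 1016 are transcripts assembled by the submitters and 116 sit on sequence not placed on a chromosome. FPKM sums ran from 621611.3 to 642049.7 per library. The sums differ between libraries, as TPM would not. Read totals are not given in the sources used here. Among 3078 genes with low values, 16.7% of values lay within 0.1 of a whole multiple of the gene's smallest value in any library, against 20% by chance. Steps of whole reads need not give whole multiples between libraries of different depth, so this comparison cannot tell whether the values hold the depth. The depth behind each value is unknown, and no counting interval or detection limit is given.

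Values were taken as log2(FPKM + 1), and the 21412 genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested. The added 1 pulls log2 changes of genes near that level toward 0. A single limma fit (limma 3.58.1 in R 4.3.3, eBayes with trend and robust) with 1 mean per genotype covered all 9 libraries, so that the groups shared an estimate of the spread. Its contrasts were TG1 minus wild type, TG2 minus wild type, the mean of both lines minus wild type, and TG2 minus TG1. The moderated tests were two-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05 on the adjusted p. Levels are given as mean FPKM with the SD over the 3 libraries of a group (n = 3), and changes as log2 differences from the fit. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

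The overlap of the lines was set against n1 x n2 / N and against 100 simulated draws in which both lines shared the wild-type libraries and no gene changed. The fit was also tested on simulated data with 200 changed genes among 21412. Of the genes changed 1.5-fold, 76% were recovered in TG1, 76% in TG2 and 83% in the mean of both lines, and at 2-fold the shares were 97%, 95% and 97%. False calls numbered 6, 2 and 5, which is 3.4%, 1.2% and 2.7% of the calls. The share of changed genes was far smaller in this simulation than among the calls in the data, and its noise held no shared batch. The adjustment depends on that share, so these rates need not hold for the counts below.

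The 24 gene lists were nitrate uptake and transport, nitrogen assimilation, ammonium transport, nitrogen regulators, tillering and strigolactone, brassinosteroid, jasmonate, diterpenoid phytoalexins, pathogenesis-related, cytokinin, auxin and root development, gibberellin, abscisic acid and water deficit, phosphate starvation, iron acquisition, DNA replication and cell division, clock, hypoxia and fermentation, green tissue, root exodermis and endodermis, root hair, secondary wall, aquaporins and heat shock. The 23 lists with at least 3 tested members were tested with camera in limma at a preset correlation between genes of 0.01, and again with an estimated correlation, with adjustment over the lists. Member counts are given over all tested genes and, where these differ, also adjusted over the list alone. No locus stood in more than 1 list (0 shared loci).

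The table gives locus IDs without gene symbols, and no reference at hand pairs these IDs with symbols (0 IDs matched). Symbols were assigned from 230 symbol and locus pairs written from general knowledge before the data were examined. Of these loci 228 are in the table and 181 were tested. A RefSeq gene table of rice (assembly ASM3414082v1) has the symbol on the same chromosome and in matching order for 175 pairs, lacks the symbol for 50 and has it on another chromosome for 5. Genes of the latter kinds are written as the locus listed as the symbol. Near-identical copies (NRT2.1 with NRT2.2, the RBCS genes, RR9 with RR10, AMT1;2 with AMT1;3, PR10a with the PR10b locus, JAZ9 to JAZ11, and NAS1 with NAS2) may share reads.

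The named genes followed a rule fixed before the data were examined: OsTCP19, DLT, LBD37, LBD39 and BU1; the 12 largest rises and the 12 largest falls in the mean of both lines among genes with a known class that passed in both lines; up to 4 members of each list by adjusted p, with any member that differed between the lines; and the 6 genes most higher and 6 most lower in TG2 than in TG1. Because the table holds no descriptions, families of genes defined by description could not be formed, and the parts of the rule that need a description drew on list genes alone.

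The following choices were also made before the data were examined: the groups, the contrasts, the lists, the filter, the threshold, and the alternative settings to be tried. These settings were a pseudocount of 0.1, no filter, a filter on a mean FPKM of at least 5, rescaling every library to the same sum (TPM), median-of-ratios scaling, quantile normalization, array weights, eBayes with neither trend nor robust, fits on the compared groups alone, a replicate block, a 2-fold minimum, camera on ranks or with an estimated correlation, and leaving out each of the 9 libraries in turn. A 1.5-fold minimum and a repeat without the genes of 3 runs of neighbouring genes were added after seeing the data. Runs of neighbouring loci were sought with medians of 20 tested loci in locus order, 20656 windows over 20884 loci, against 100 shuffles of the locus order. Raw reads were not analysed here.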

Results

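Root RNA was profiled in the rice wild type ZH11 and in 2 lines, TG1 and TG2, that overexpress OsTCP19, a transcription factor of the plant-specific TCP family. The series title concerns how rice adapted to soils that differ in nitrogen. The comparisons below ask which root transcripts differ from wild type in lines with raised OsTCP19, and whether both lines change alike. No transformed control without the OsTCP19 transgene is among the libraries. Effects of transformation or of background shared by both lines therefore cannot be separated from those of OsTCP19. Each genotype had 3 libraries from 14-day-old seedlings. No growth batch or harvest date is given in the sources used here, so a batch shared by the libraries of a genotype cannot be separated from the genotype in any of the counts that follow. FPKM sums per library ran from 621611.3 to 642049.7, and the read depth is unknown. Across genes, which are not independent replicates, log2 values correlated at 0.996 to 0.997 between libraries of a group, at 0.968 to 0.971 between wild type and TG1, at 0.959 to 0.966 between wild type and TG2, and at 0.984 to 0.986 between the lines. The first 2 principal components held 67.04% and 21.25% of the variance.

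OsTCP19 (LOC_Os06g12230) rose in both lines. Its level was 5.08 ± 0.225 FPKM in wild type (SD, n = 3), 34.4 ± 0.613 in TG1 and 27.2 ± 0.840 in TG2, which is 6.77 and 5.36 times the wild-type level, and each of the 6 line libraries lay above each of the 3 wild-type libraries. The log2 change was 2.54 in TG1, 2.22 in TG2 and 2.38 in their mean (SE 0.0341, adjusted p = 8.13e-15), and TG2 lay below TG1 by a log2 difference of -0.33 (adjusted p = 2.59e-05). The locus listed as DLT (LOC_Os06g03710), a GRAS-family regulator of tillering, fell from 2.84 ± 0.178 to 1.38 ± 0.210 and 1.58 ± 0.107 FPKM, a mean log2 change of -0.63 (adjusted p = 3.27e-06). Among LOB-domain proteins tied to nitrogen, the locus listed as LBD39 (LOC_Os03g41330) fell from 107.0 ± 4.25 to 54.4 ± 2.42 and 63.8 ± 2.395 FPKM. The locus listed as LBD37 (LOC_Os03g33090) rose in TG1 from 13.7 ± 0.195 to 18.1 ± 0.498 FPKM and stood at 13.4 ± 0.277 in TG2, where it did not pass (log2 change -0.02, adjusted p = 0.607, and 0.011 with libraries rescaled to TPM). BU1 (LOC_Os06g12210), a near neighbour of OsTCP19, averaged 0.187 FPKM in wild type, was listed at 0 in all 6 line libraries and was too low to be tested.

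**Figure D1:**
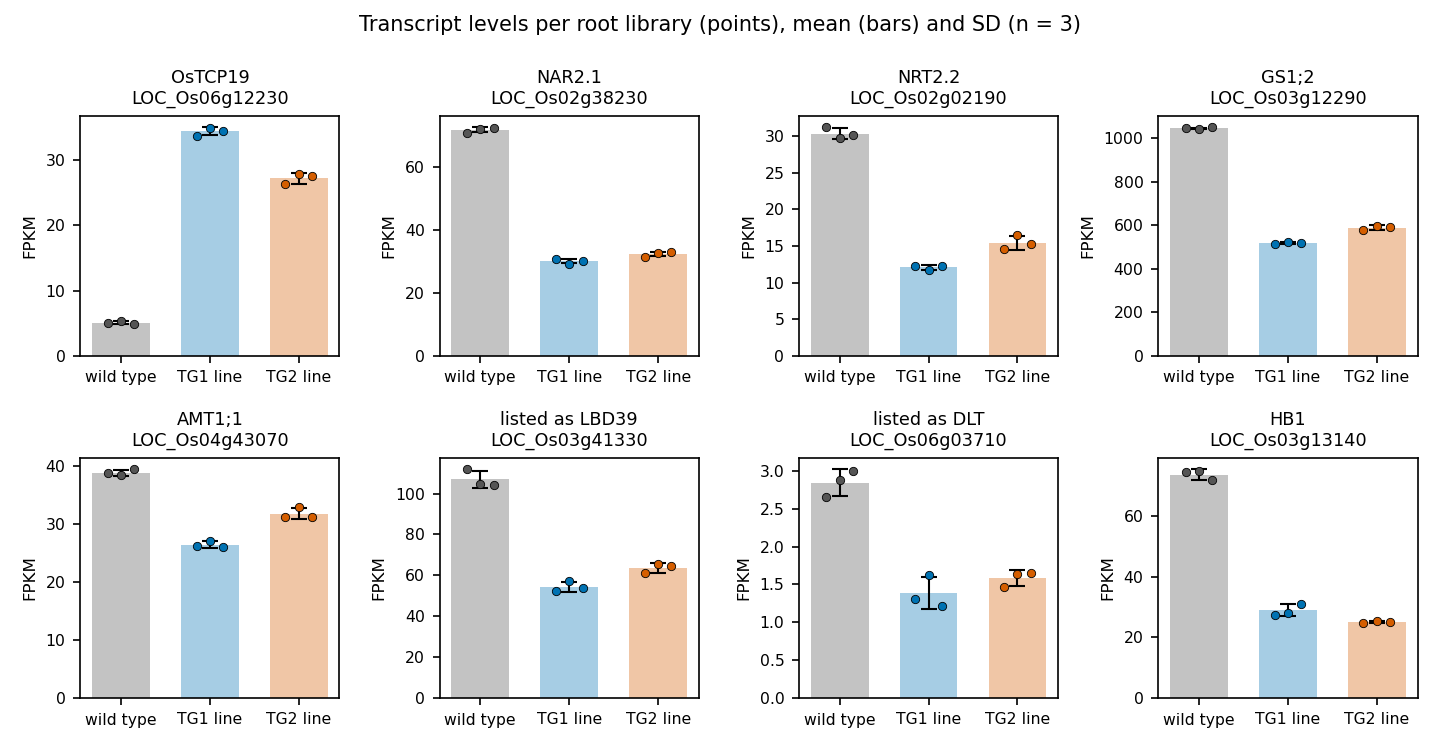
FPKM of OsTCP19 and of 7 named genes in each library (points) of the wild type, TG1 and TG2, with bars for the mean and error bars for the SD (n = 3), each panel on its own axis from 0. OsTCP19 averages 5.08 FPKM in wild type against 34.4 in TG1 and 27.2 in TG2, and the other 7 genes are lower in both lines than in wild type.

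In TG1 roots, photosynthesis transcripts were the group with the highest median rise among the lists, while genes of nitrogen assimilation, of DNA replication and of water channels fell together. All 8 green tissue markers rose, such as RBCS (LOC_Os12g17600), a small subunit of Rubisco, from 22.2 ± 1.51 to 91.2 ± 1.86 FPKM, and the list median was 1.62 (adjusted p = 6.76e-09, and adjusted p = 0.0926 with an estimated correlation). Of 14 tested nitrogen assimilation genes 10 fell and 2 rose, with a median of -0.53 (adjusted p = 6.66e-04, and adjusted p = 0.0767 with an estimated correlation). All 13 DNA replication and cell division genes fell (median -0.43, adjusted p = 1.51e-04, and adjusted p = 0.0767 with an estimated correlation), as did all 7 aquaporins (median -0.34, adjusted p = 4.2e-04, and adjusted p = 0.279 with an estimated correlation). In the clock list 8 of 9 genes rose and 1 fell (median 0.17, adjusted p = 0.0148, and adjusted p = 0.279 with an estimated correlation). In the iron acquisition list 7 of 9 genes rose and 1 fell (median 0.52, adjusted p = 0.0262, and adjusted p = 0.228 with an estimated correlation). YSL15 (LOC_Os02g43410), which takes up iron bound to phytosiderophores, went from 0.413 ± 0.0321 to 2.297 ± 0.203 FPKM, and the locus listed as TOM1 (LOC_Os11g04020), a phytosiderophore exporter, from 0.970 ± 0.364 to 3.56 ± 0.177.

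Of 21412 tested genes 13200 (61.6%) passed in TG1 against wild type, 6104 higher and 7096 lower. Most of these changes were small, with a median absolute log2 change of 0.30, and 684 reached 2-fold, 410 higher and 274 lower. With an estimated correlation 0 of the 23 tested lists passed in limma camera, and 4 had an unadjusted p under 0.05. The iron acquisition call ended without TG1 replicate 1 (adjusted p = 0.0521), replicate 2 (0.0642) or replicate 3 (0.0676), and without the neighbouring genes of 3 chromosome runs (0.0622), its adjusted p running from 0.014 to 0.647 over the alternatives. The clock call ended under a filter on a mean FPKM of 5 (adjusted p = 0.0689, range 8.89e-04 to 0.279).

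In TG2 roots, nitrogen assimilation, water channels and cell division were again lower and green tissue genes higher, the defence lists passed as higher, and genes of the secondary wall and of the exodermis and endodermis fell. Of 14 nitrogen assimilation genes 12 fell and 1 rose (median -0.38, adjusted p = 5.98e-05, and adjusted p = 0.0761 with an estimated correlation). All 7 aquaporins fell (median -0.57, adjusted p = 5.98e-05, and adjusted p = 0.242 with an estimated correlation). All 8 green tissue genes rose (median 0.80, adjusted p = 1.13e-05, and adjusted p = 0.211 with an estimated correlation), and 12 of 13 DNA replication genes fell (median -0.33, adjusted p = 0.00157, and adjusted p = 0.119 with an estimated correlation). All 6 diterpenoid phytoalexin genes rose (median 0.63, adjusted p = 0.00967, and adjusted p = 0.211 with an estimated correlation), and 5 of 9 pathogenesis-related genes rose while 2 fell (median 0.53, adjusted p = 0.0415, and adjusted p = 0.275 with an estimated correlation). Neither list passed in TG1, but genes of both rose there too. In TG1 4 of 6 phytoalexin genes rose and 0 fell (median 0.38, adjusted p = 0.0503, and 0.0465 with a replicate block and 0.279 with an estimated correlation). Of 9 pathogenesis-related genes 5 rose in TG1 and 2 fell, and 6 rose and 2 fell adjusted over the list alone (median 0.17, adjusted p = 0.129). The phytoalexin list did not pass between the lines (adjusted p = 0.161, range 0.0499 to 0.404 over the alternatives, past the threshold with no filter). Of its 6 genes 3 were higher in TG2 than in TG1 and 0 lower. WRKY76 (LOC_Os09g25060), a WRKY regulator of defence, went from 24.8 ± 1.2 to 80.3 ± 4.61 FPKM. All 4 secondary wall genes fell (median -0.86, adjusted p = 0.00321, and adjusted p = 0.211 with an estimated correlation), among them BC1 (LOC_Os03g30250), a COBRA-like protein of cellulose assembly, from 6.78 ± 0.0945 to 2.19 ± 0.172 FPKM. All 3 exodermis and endodermis genes fell (median -0.43, adjusted p = 0.017, and adjusted p = 0.25 with an estimated correlation), with CASP1 (LOC_Os04g58760), a scaffold protein of the Casparian strip, going from 10.3 ± 0.940 to 4.02 ± 0.497 FPKM. The other lists past the threshold were clock, which was higher, and nitrate uptake and transport, tillering and strigolactone, cytokinin, auxin and root development, and hypoxia and fermentation, which were lower (adjusted p from 0.0122 for clock to 0.0415 for tillering). With an estimated correlation the adjusted p was 0.25 for clock, nitrate and cytokinin, 0.255 for tillering, and 0.211 for auxin and for hypoxia.

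In TG2 14148 genes (66.1%) passed against wild type, 7231 higher and 6917 lower, with a median absolute log2 change of 0.31, and 873 reached 2-fold, 326 higher and 547 lower. In limma camera 0 of 23 lists passed with an estimated correlation and 5 had an unadjusted p under 0.05. The tillering call ended without wild-type replicate 2 (adjusted p = 0.0532) or TG2 replicate 1 (0.0677) and under a filter on a mean FPKM of 5 (0.153), and ran from 0.0093 to 0.255 over the alternatives, and the pathogenesis-related call ended on ranks (0.112), under that filter (0.0675) and without TG2 replicate 3 (0.0526), and ran from 0.0203 to 0.275. The auxin call ended under the same filter (adjusted p = 0.136, range 0.00958 to 0.211), the hypoxia call on ranks (0.0994, range 0.014 to 0.211) and the cytokinin call without the genes of 3 chromosome runs (0.0768, range 0.0104 to 0.25). In 2 lists that did not pass, jasmonate (median -0.02, mean 0.014) and phosphate starvation (median -0.06, mean 0.107), the mean differed in sign from the median and from the test direction, which was down.

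Most genes that changed in both lines changed the same way. The 10288 shared genes comprised 4907 higher and 5381 lower, and 425 changed in opposite directions, where independence would give 2061.4 and 2292.3. At 2-fold 183 genes were higher and 200 lower in both lines, with 0 opposite, against 6.2 and 7 for independent lists. Genes of nitrate and ammonium handling were among those lower in both, such as NAR2.1 (LOC_Os02g38230), the partner protein of high-affinity nitrate transporters, at 71.9 ± 0.762, 30.2 ± 0.740 and 32.4 ± 0.748 FPKM in wild type, TG1 and TG2. The locus listed as GA3ox2 (LOC_Os01g08220), a gibberellin biosynthesis enzyme, was at 3.15 ± 0.0529, 0.223 ± 0.0379 and 0.193 ± 0.0577 FPKM. SPX2 (LOC_Os02g10780), of the SPX family of phosphate sensors, was at 0.947 ± 0.146, 5.27 ± 0.420 and 5.23 ± 0.168 FPKM. Both comparisons share the wild-type libraries. In 100 simulated draws with shared controls and no changed gene the overlap averaged 0.03 and reached at most 1, the correlation of log2 changes across genes was 0.501 against 0.802 measured (Spearman 0.459 against 0.81), and the covariance was 0.00341 against 0.155, a difference of 0.152. With no changed gene hardly any gene can pass in either line, so the simulated overlap does not show what shared controls add to the 10288 genes. The 3 wild-type libraries cannot be divided into sets of at least 2, so the part that shared controls add to the covariance could not be measured directly.

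The labels give both lines the same genotype, and their mean against wild type asks for their average change. Its SE and adjusted p rest on the spread between libraries within a group. Variation between the lines does not enter them, so they do not measure how well a change is shared by the lines. Over the 181 tested list genes 47 rose, 102 fell and 32 did not pass. For 122 of the 181 tested genes all 6 line libraries lay on the same side of all 3 wild-type libraries, which chance gives for 2.38% of genes. Of all 21412 genes 14477 (67.6%) passed, 7033 higher and 7444 lower, with a median absolute log2 change of 0.28, and 687 reached 2-fold, 327 higher and 360 lower. Of 23 lists 7 passed, 3 up and 4 down. In limma camera 0 passed with an estimated correlation and 4 had an unadjusted p under 0.05. Over the 21 alternatives each of the 7 lists had its highest adjusted p with the estimated correlation, and the lowest ran from 2.73e-09 for green tissue to 0.0143 for auxin and root development. A count of genes that changed in the mean includes genes that changed in a single line, and 3759 of the 10288 shared genes also differed between the lines. Of 131 named genes past the threshold 7 lost the call when a single library was left out: D3 (LOC_Os06g06050), GDH2 (LOC_Os04g45970), BRI1 (LOC_Os01g52050), MAS (LOC_Os04g10010), PRR73 (LOC_Os03g17570), RR4 and the locus listed as DMAS1 (LOC_Os03g13390).

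Nitrogen assimilation genes fell as a list in the mean of both lines. Of 14 tested genes 11 fell, 1 rose and 2 did not pass, and adjusted over the list alone 12 fell and 1 rose. The median was -0.50 (adjusted p = 7.94e-05, and adjusted p = 0.0667 with an estimated correlation). GS1;2 (LOC_Os03g12290), a cytosolic glutamine synthetase, fell from 1045 ± 2.96 to 517 ± 3.77 and 589 ± 11.7 FPKM, and the locus listed as AS1 (LOC_Os03g18130), an asparagine synthetase, from 1043 ± 19.4 to 546 ± 2.37 and 617 ± 27.5. The locus listed as NIR1 (LOC_Os01g25484), a nitrite reductase, fell from 700.1 ± 10.7 to 361 ± 3.30 and 402 ± 18.5 FPKM. The locus listed as NIR2 (LOC_Os02g52730) fell most of the list in the mean (log2 change -2.26), with 23.0 ± 0.689 FPKM in wild type, 18.5 ± 1.101 in TG1 and 0.297 ± 0.0950 in TG2. The gene of the list that rose was the locus listed as AS2 (LOC_Os06g15420), from 21.6 ± 0.570 to 24.8 ± 0.879 and 28.5 ± 1.32 FPKM.

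Transport of nitrate and ammonium did not pass as lists, although most members fell. For nitrate 5 of 8 tested genes fell and 1 rose (median -0.24, adjusted p = 0.0611, range 0.0163 to 0.338 over the alternatives, past the threshold with no filter, with the filter on a mean FPKM of 5 and on TPM). NRT2.2 (LOC_Os02g02190), a high-affinity nitrate transporter, fell from 30.3 ± 0.774 to 12.1 ± 0.327 and 15.5 ± 0.964 FPKM, while NAR2.2 (LOC_Os04g40410) rose from 0.763 ± 0.316 to 2.47 ± 0.120 and 3.45 ± 0.490. For ammonium 5 of 8 genes fell and 1 rose (median -0.42, adjusted p = 0.0762, range 0.0376 to 0.361, past with no filter), with AMT1;3 (LOC_Os02g40730) going from 223 ± 2.49 to 124 ± 2.91 and 157 ± 2.304 FPKM. Of 9 nitrogen regulators 5 fell and 3 rose (median -0.12, adjusted p = 0.517). NGR5 (LOC_Os05g32270), a nitrogen-responsive regulator of tillering, rose from 11.1 ± 0.177 to 16.8 ± 0.693 and 16.91 ± 1.08 FPKM.

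Cell division genes fell in the mean of both lines, all 13 of them (median -0.32, adjusted p = 2.03e-04, and adjusted p = 0.0667 with an estimated correlation). CDKB2;1 (LOC_Os08g40170), a cyclin-dependent kinase of mitosis, fell from 15.2 ± 0.947 to 8.12 ± 0.355 and 7.94 ± 0.592 FPKM, and CYCB1;1 (LOC_Os01g59120), a mitotic cyclin, from 8.10 ± 0.483 to 4.62 ± 0.374 and 4.69 ± 0.125. Auxin and root development genes were lower, 5 of 8 with 3 not past (median -0.22, adjusted p = 0.0425, and adjusted p = 0.26 with an estimated correlation). PIN2 (LOC_Os06g44970), an auxin efflux carrier, fell from 6.08 ± 0.165 to 3.02 ± 0.141 and 2.71 ± 0.186 FPKM, and GH3-2 (LOC_Os01g55940), which conjugates auxin to amino acids, from 105 ± 2.51 to 62.2 ± 1.89 and 69.2 ± 3.28. The auxin call ended without wild-type replicate 2 (adjusted p = 0.0501), without TG1 replicate 3 (0.0534) and under a filter on a mean FPKM of 5 (0.102), its adjusted p running from 0.0143 to 0.26. All 7 aquaporins fell (median -0.54, adjusted p = 7.94e-05, and adjusted p = 0.26 with an estimated correlation), with PIP1;3 (LOC_Os02g57720), a plasma membrane water channel, going from 297 ± 8.41 to 161 ± 3.06 and 201 ± 10.2 FPKM.

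No other hormone list passed in the mean of both lines. Of 8 gibberellin genes 5 fell and 2 rose (median -0.34, adjusted p = 0.167). The loci listed as GA20ox1 (LOC_Os03g63970) and GA3ox2, which make gibberellin, fell by 1.41 and 1.78 on the log2 scale, and the loci listed as GA2ox1 (LOC_Os05g06670) and GA2ox3 (LOC_Os01g55240), which inactivate it, rose by 0.83 and 0.41. Of 9 brassinosteroid genes 5 fell, and 4 adjusted over the list alone (median -0.14, adjusted p = 0.157), among them the biosynthesis genes DWARF4 (LOC_Os03g12660, log2 change -0.82) and BRD1 (LOC_Os03g40540, -0.62). Of 6 cytokinin genes 3 fell and 2 rose (median -0.22, adjusted p = 0.201), with the response regulator RR9 (LOC_Os11g04720) at -0.53. Of 11 jasmonate genes 4 fell and 2 rose (median -0.06, adjusted p = 0.365), with the locus listed as MYC2 (LOC_Os10g42430) at -0.44 and JAZ10 (LOC_Os03g08320) at 0.48. Of 6 genes of abscisic acid and water deficit 3 fell and 1 rose (median -0.08, adjusted p = 0.257), with SALT (LOC_Os01g24710), a lectin induced by salt, going from 115 ± 2.19 to 63.5 ± 1.62 and 26.6 ± 0.797 FPKM. Of 7 tillering and strigolactone genes 4 fell (median -0.10, adjusted p = 0.0762), with D14 (LOC_Os03g10620), the strigolactone receptor, going from 360.4 ± 7.73 to 229.6 ± 5.23 and 219 ± 18.8 FPKM.

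All 8 green tissue genes rose in the mean of both lines (median 1.247, adjusted p = 4.03e-07, and adjusted p = 0.147 with an estimated correlation). All 8 were also expressed in each wild-type root library, at 5.41 FPKM or more. CAB2R (LOC_Os01g41710), a light-harvesting protein, went from 366 ± 15.4 to 1064 ± 25.6 and 640.0 ± 39.3 FPKM, and the locus listed as RBCS3 (LOC_Os12g19381) from 304 ± 9.74 to 993 ± 8.22 and 665 ± 9.25. The clock list rose with them, 7 of 9 genes higher and 1 lower (median 0.20, adjusted p = 0.0143, and adjusted p = 0.312 with an estimated correlation), led by PRR95 (LOC_Os09g36220), from 76.0 ± 0.490 to 108.5 ± 0.297 and 108.3 ± 1.31 FPKM. Diterpenoid phytoalexin genes rose as a list, 5 of 6 tested and 6 adjusted over the list alone (median 0.49, adjusted p = 0.0171, and adjusted p = 0.26 with an estimated correlation). CYP76M8 (LOC_Os02g36070), a cytochrome P450 of that pathway, went from 4.54 ± 0.0529 to 6.95 ± 0.0611 and 9.73 ± 0.547 FPKM, and CPS4 (LOC_Os04g09900), a diterpene cyclase, from 3.66 ± 0.147 to 6.46 ± 0.251 and 6.22 ± 0.448. The phytoalexin call ended under a filter on a mean FPKM of 5 (adjusted p = 0.0735, range 1.05e-04 to 0.26).

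The remaining lists did not pass in the mean of both lines. Of 9 pathogenesis-related genes 6 rose and 2 fell, and 6 rose and 3 fell adjusted over the list alone (median 0.46, adjusted p = 0.0611). Of 4 hypoxia and fermentation genes 3 fell and 1 rose (median -0.52, adjusted p = 0.0611), with the hemoglobin HB1 (LOC_Os03g13140) going from 73.8 ± 1.69 to 28.9 ± 1.97 and 25.1 ± 0.226 FPKM. All 4 secondary wall genes fell in the mean (median -0.34, adjusted p = 0.0505), but in TG1 2 of them rose and 1 fell (median 0.19), so that this fall was not shared by the lines. All 3 exodermis and endodermis genes fell in the mean (median -0.29, adjusted p = 0.0581), 1 of them past the threshold in TG1 and all 3 in TG2. All 3 tested heat shock genes fell (median -0.36, adjusted p = 0.0762). Of 10 phosphate starvation genes 5 fell and 3 rose (adjusted p = 0.517), and the median of -0.16, the mean of 0.003 and a test direction of down did not share a sign. Of 9 iron acquisition genes 4 rose and 4 fell (adjusted p = 0.706), with a median of -0.02, a mean of 0.109 and a test direction of up. The root hair list had 2 tested genes, too few for the test, and both fell: CSLD1 (LOC_Os10g42750), a cellulose synthase-like protein of root hairs, from 7.72 ± 0.241 to 4.29 ± 0.221 and 4.12 ± 0.388 FPKM, and EXPA17 (LOC_Os06g01920), a root hair expansin, from 1.22 ± 0.172 to 1.16 ± 0.200 and 0.0733 ± 0.0289, a fall that passed in TG2 and not in TG1 (adjusted p = 0.722). Several of these lists passed under some alternatives, no filter and TPM for each among them. Secondary wall ran from 0.011 to 0.312 (for example 0.0472 without wild-type replicate 1, and 0.044, 0.0417 and 0.0472 without TG2 replicate 1, 2 or 3). Exodermis and endodermis ran from 0.0239 to 0.338 (0.044 and 0.0417 without TG2 replicate 1 or 2). Pathogenesis-related ran from 0.028 to 0.338 (0.0472 without wild-type replicate 1 and 0.0465 without TG2 replicate 1) and hypoxia from 0.028 to 0.26. With no filter the tillering (adjusted p = 0.028, range 0.028 to 0.338) and brassinosteroid lists (0.0406, range 0.0406 to 0.312) also passed.

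**Figure D2:**
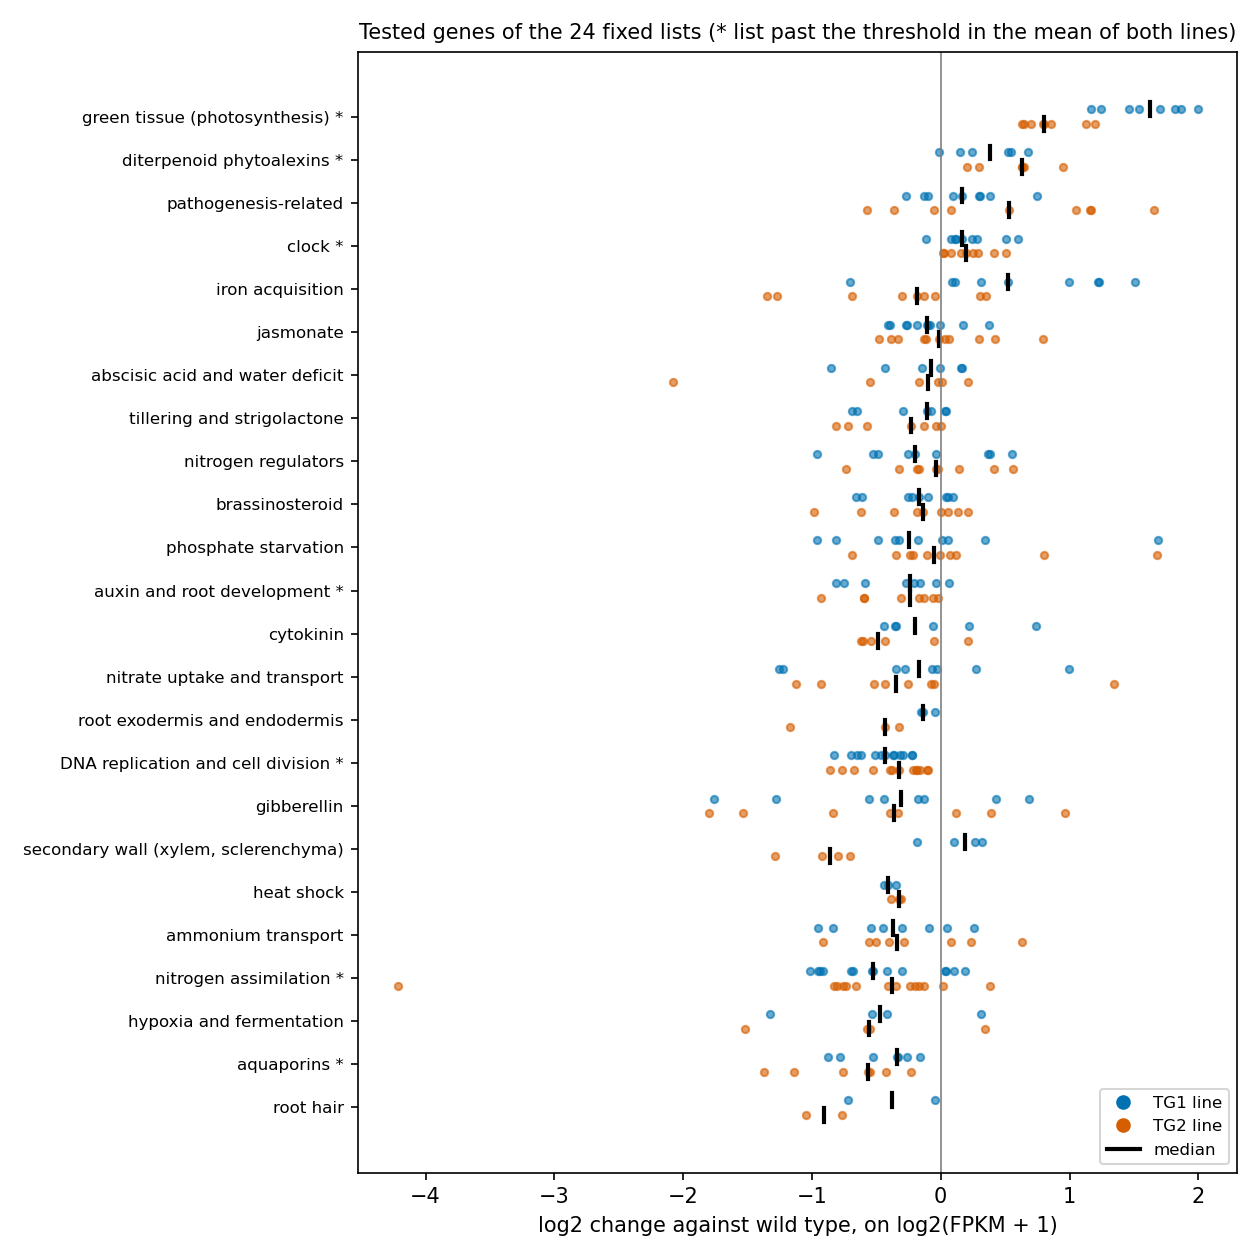
Log2 change against wild type of each tested gene of the 24 lists in TG1 (blue) and TG2 (orange), with list medians as black bars and an asterisk on the 7 lists past the threshold in the mean of both lines. Green tissue medians lie highest, at 1.62 in TG1 and 0.80 in TG2, and the secondary wall medians stand at 0.19 and -0.86.

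The lines differed from each other most in iron acquisition, secondary wall and green tissue genes, all lower in TG2 than in TG1. Of 9 iron acquisition genes 7 were lower (median -0.92, adjusted p = 1.95e-06, and adjusted p = 0.0528 with an estimated correlation). NAS1 (LOC_Os03g19427), a nicotianamine synthase, stood at 3.52 ± 0.180 FPKM in wild type, 5.48 ± 0.530 in TG1 and 0.777 ± 0.191 in TG2. All 4 secondary wall genes were lower (median -1.05, adjusted p = 5.63e-06, and adjusted p = 0.0771 with an estimated correlation), for example the cellulose synthase CESA4 (LOC_Os01g54620), which rose in TG1 to 13.4 ± 0.166 from 10.6 ± 0.246 FPKM and fell in TG2 to 6.09 ± 0.240. All 8 green tissue genes were lower (median -0.68, adjusted p = 4.31e-10, and adjusted p = 0.0771 with an estimated correlation). All 3 exodermis and endodermis genes were lower too (median -0.28, adjusted p = 0.00217, and adjusted p = 0.301 with an estimated correlation).

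Smaller differences between the lines passed in 4 further lists. Of 10 phosphate starvation genes 5 were higher in TG2 and 5 did not pass (median 0.18, adjusted p = 0.00848, and adjusted p = 0.219 with an estimated correlation). Of 9 pathogenesis-related genes 5 were higher in TG2 and 2 lower (median 0.15, adjusted p = 0.0204, and adjusted p = 0.359 with an estimated correlation), with WRKY62 (LOC_Os09g25070), a WRKY regulator of defence, at 39.0 ± 1.03, 44.0 ± 0.160 and 88.9 ± 4.07 FPKM in wild type, TG1 and TG2. Of 6 cytokinin genes 4 were lower in TG2 (median -0.14, adjusted p = 0.0204, and adjusted p = 0.353 with an estimated correlation). Of 7 aquaporins 4 were lower and 2 higher in TG2 (median -0.27, adjusted p = 0.0378, and adjusted p = 0.434 with an estimated correlation). In the nitrogen assimilation list, which did not pass here (adjusted p = 0.289), the median was 0.16, the mean -0.18 and the test direction up, since 8 of 14 genes were higher in TG2 and the NIR2 locus was lower by a log2 difference of -3.91. Median, mean and test direction also differed in sign, in lists that did not pass, for nitrate (0.05, -0.01, down), clock (-0.03, -0.005, up) and auxin (0.002, -0.007, down).

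Between the lines 8172 genes (38.2%) passed, 4353 higher and 3819 lower in TG2, and 243 reached 2-fold, 39 higher and 204 lower. Of the 8 lists 2 were up and 6 down, 0 passed in limma camera with an estimated correlation, and 4 then had an unadjusted p under 0.05. The iron call ended under a filter on a mean FPKM of 5 (adjusted p = 0.264, range 3.2e-07 to 0.264) and the cytokinin call without the genes of 3 chromosome runs (0.158, range 0.0142 to 0.353), with no filter (0.0635) and on ranks (0.0566). The pathogenesis-related call ended on ranks (0.186, range 0.00502 to 0.359), and the aquaporin call under that filter (0.0501), median-of-ratios scaling (0.0607), quantile normalization (0.111) and ranks (0.215, range 0.0229 to 0.434).

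**Figure D3:**
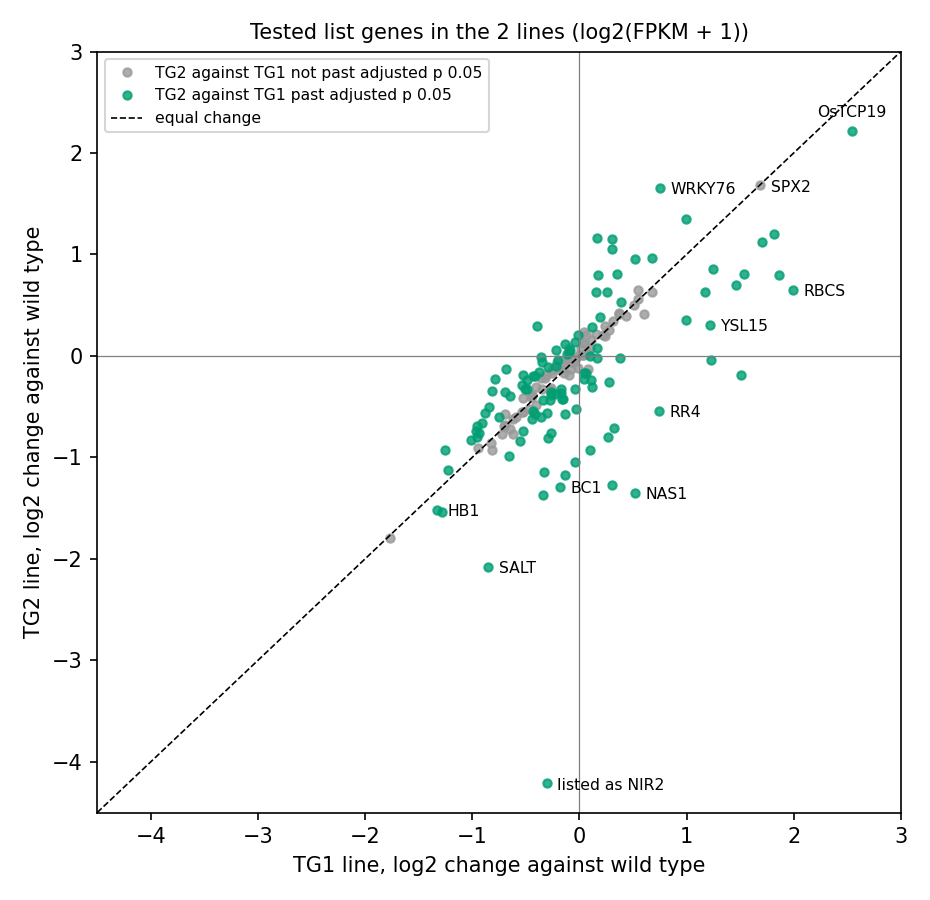
Log2 change against wild type of each tested list gene in TG1 (horizontal) and TG2 (vertical), with the line of equal change dashed; green points passed adjusted p 0.05 for TG2 against TG1. OsTCP19 lies at 2.54 and 2.22, and the locus listed as NIR2 lies far below the diagonal, at -0.30 and -4.21.

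Some differences between the lines ran through stretches of neighbouring loci. On chromosome 1, 54 tested loci from LOC_Os01g71710 to LOC_Os01g72610 were higher in TG1 than in TG2, all 54 past the threshold, with a median ratio of 1.89 (quartiles 1.72 and 2.14). The median ratio to wild type was 1.94 in TG1 and 1 in TG2. This stretch holds the cytokinin response regulator RR4 (LOC_Os01g72330), at 19.1 ± 1.204, 32.5 ± 1.05 and 12.7 ± 0.225 FPKM in wild type, TG1 and TG2, and the locus listed as IRO2 (LOC_Os01g72370), a regulator of iron uptake, at 2.5 ± 0.243, 8.97 ± 0.265 and 2.07 ± 0.179. On chromosome 8, 17 tested loci from LOC_Os08g25839 to LOC_Os08g26620 had median ratios to wild type of 4.73 in TG1 and 8.36 in TG2, and 15 of them were higher in TG2 than in TG1. On chromosome 10, 17 tested loci from LOC_Os10g31460 to LOC_Os10g31730 had median log2 changes of -0.76 in TG1, where 15 passed as lower, and -1.18 in TG2, where all 17 did. In a scan of 20656 windows of 20 loci, 85 windows in TG1, 38 in TG2 and 114 between the lines exceeded the highest absolute median of 100 shuffles (0.447, 0.523 and 0.24). The edges of these 3 stretches were set after the values were seen.

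**Figure D4:**
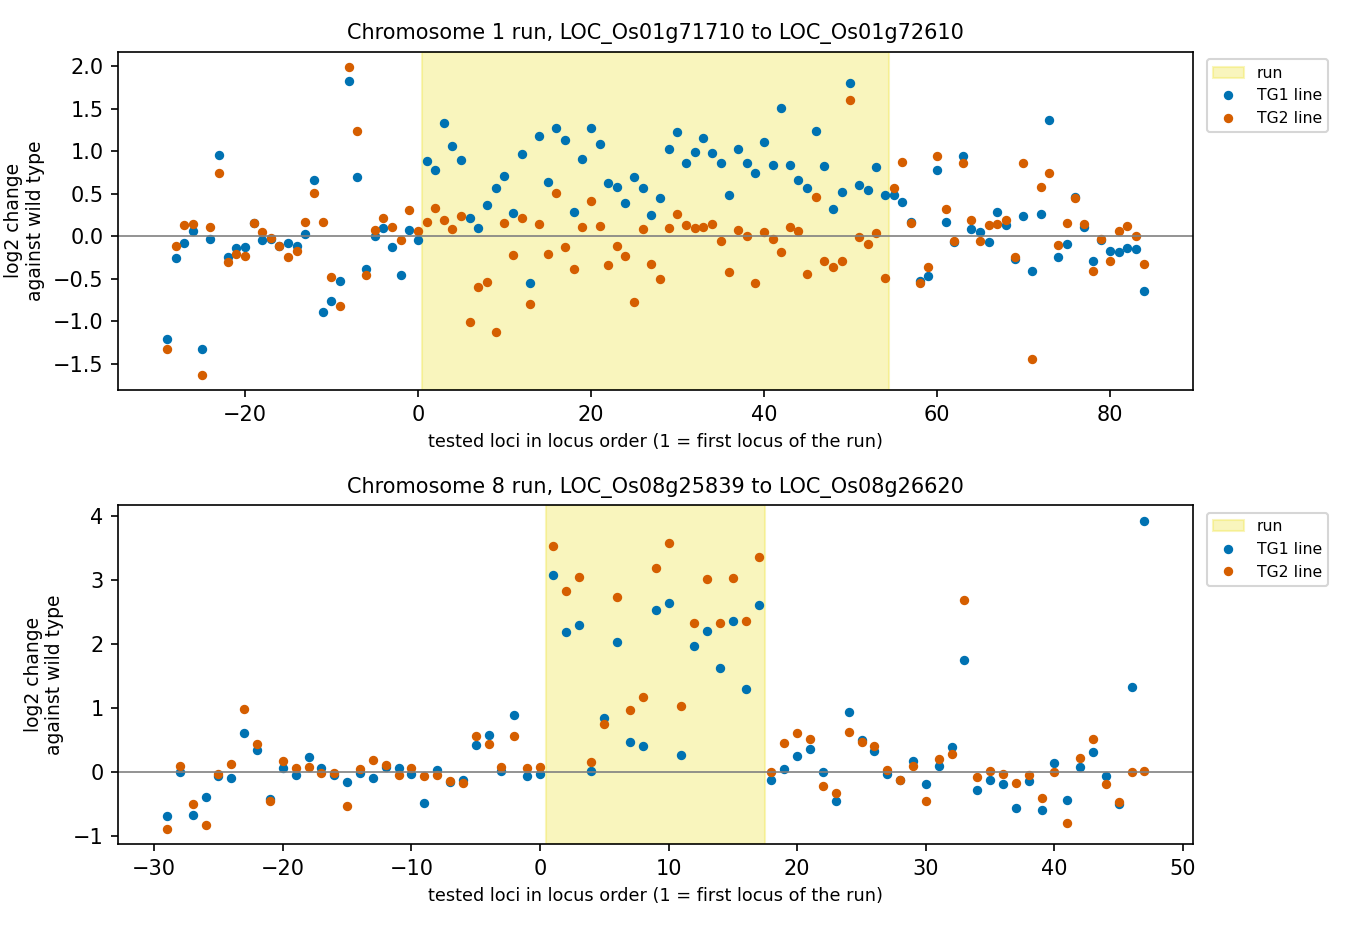
Log2 change against wild type of tested loci in locus order around the chromosome 1 and chromosome 8 stretches (shaded), for TG1 in blue and TG2 in orange. On chromosome 1 the medians inside are 0.83 in TG1 and 0.001 in TG2, and on chromosome 8 they are 2.03 and 2.74.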

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

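All tests weighed here were chosen after the result was seen, except the splits of the libraries, which were planned, and the summed level of low loci on chromosome 1, whose values had not been seen, and the single genes were limited to differences of at least 1.5-fold after seeing the data. What marked each result was a tested difference between the lines, whose effects against the same wild type can be compared directly. Between TG2 and TG1 8172 genes differed. Splits of these 6 libraries into 3 and 3 are too few for a share under 0.05: 1 of the 10 splits, the real one, gave as many genes, and the highest of the others gave 1.

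Among the gene lists, medians of TG2 minus TG1 were -1.05 for secondary wall, -0.92 for iron acquisition, -0.68 for green tissue, -0.28 for exodermis and endodermis, -0.27 for aquaporins and -0.14 for cytokinin. They were 0.18 for phosphate starvation and 0.15 for pathogenesis-related genes.

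Secondary wall genes differed by -1.11 (BC1), -1.03 (CESA7, LOC_Os10g32980), -1.07 (CESA9, LOC_Os09g25490) and -1.03 (CESA4). Iron genes differed by -1.87 (NAS1), -1.58 (NAS2, LOC_Os03g19420), -0.91 (YSL15), -0.64 (YSL2, LOC_Os02g43370), -1.70 (the IRO2 locus) and -1.27 (the TOM1 locus). Green tissue genes differed by -0.62 (the locus listed as PSBS1, LOC_Os01g64960), -1.07 (the locus listed as LHCB, LOC_Os01g52240), -1.34 (RBCS), -0.73 (CAB2R) and -0.76 (RCA, LOC_Os11g47970). Defence and jasmonate genes differed by 0.91 (WRKY76), 1.00 (WRKY62), 0.75 (the locus listed as WRKY45, LOC_Os05g25770), 0.86 (the locus listed as PR1a, LOC_Os07g03710), 0.63 (JAZ10) and 0.69 (AOS2, LOC_Os03g12500). The NIR2 locus differed by -3.91, SALT by -1.23 and RR4 by -1.29. Water channel, Casparian strip and root hair genes differed by -1.04 (TIP2;1, LOC_Os02g44080), -0.81 (PIP2;1, LOC_Os07g26690), -1.03 (CASP1) and -1.0 (EXPA17).

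The chromosome 1 stretch was mostly higher in TG1 than in TG2 and wild type: TG1 was at least 1.5 times TG2 at 94.4% of its 54 loci and at least 1.5 times wild type at 77.8%, with 51 past the threshold above wild type and 1 below. A response to raised OsTCP19 shared by both lines is argued against by the TG2 median of 0.001, and library scaling by the 0.044 difference between the lines at 100 flanking loci. The lower iron list in TG2 does not rest on the IRO2 locus inside the stretch as a list member. Without it the camera adjusted p was 2.44e-05 (8 genes, median -0.78, adjusted p = 0.0771 with an estimated correlation). The iron call in TG1 against wild type is lost without it (median 0.41, camera adjusted p = 0.0648). Leaving the locus out of the list cannot exclude an effect of this regulator of iron uptake on the other iron genes, which was not tested. An added copy of the segment in TG1 may account for the stretch. The summed FPKM of its 21 untested low loci was also higher in TG1, 1.78 times TG2 and 1.54 times wild type, with 15 of 21 loci above TG2. These sums were low, at 2.69, 4.16 and 2.34 FPKM in wild type, TG1 and TG2, with SDs of 0.284, 0.507 and 0.0945. A regional change of transcription without added DNA would raise these loci too and stays open, as DNA was not analysed here. No link of the stretch to the transgene was tested.

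The chromosome 8 stretch was higher in both lines than in wild type, and further so in TG2, by a median log2 difference of 0.698 between the lines. A response graded by the OsTCP19 transcript level is argued against, because that level was lower in TG2 than in TG1. OsTCP19 protein is not part of these data. Added copies of the segment cannot be told apart from a local rise in transcription: the 18 untested low loci gave a TG1 to wild type ratio of 2.02, but on sums of 0.27, 0.547 and 1.02 FPKM with SDs of 0.161, 0.25 and 0.1, and 1 expressed locus inside, LOC_Os08g25864, was at 13.8, 13.9 and 15.5 FPKM in wild type, TG1 and TG2. It did not change in TG1 (log2 of 0.011) and rose in TG2 by a log2 of 0.158 against a median of 2.736 for the stretch, which a copy of the whole segment leaves unaccounted for. An effect of OsTCP19 that is not graded by its transcript level, and a difference in background between both lines and the wild type, may also account for the stretch and were not tested.

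Green tissue genes were higher in both lines than in wild type, reaching 1064 FPKM for CAB2R and 993 for the RBCS3 locus in TG1. Shoot tissue of the same profile in both lines, as the only change in these genes, is argued against. It would add the genes in the same ratio of TG2 to TG1. The ratios ran from 0.19 for RBCS to 0.593 for CAB1R (LOC_Os09g17740), with a chi-square of 64.8 per degree of freedom over 7. Library scaling is argued against by the median change of all tested genes, -0.0044. Shoot tissue of the same profile combined with changes of these genes in the root itself stays open, because the ratios take the wild-type level as the root level. Shoot tissue whose profile differed between the lines also stays open. A response of root plastids to OsTCP19 or to light at the roots may account for the rise but was not tested.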

How the results depend on the processing

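The 1.5-fold minimum and the repeat without 3 runs of genes were tests chosen after the result was seen; the others were planned. Of 148 values of counts and of OsTCP19 under alternatives 135 stayed within their limits, which were 1.5 times the main value for counts, and the same direction and side of the threshold for OsTCP19. Of 6073 values of named genes 5867 kept direction and side of the threshold, 180 lost the call, 11 gained it and 15 changed sign; of 1384 values of lists the numbers were 1270, 62, 31 and 21. Counts of changed genes rest on small changes. A 1.5-fold minimum left 2316 genes in TG1, 2781 in TG2, 2449 in the mean of both lines, 844 between the lines and 1581 in both lines, and a 2-fold minimum left 684, 873, 687, 243 and 383, by construction. These minimums apply to counts of genes alone, not to OsTCP19, lists or named genes. The number of lists in the mean went from 7 to 16 with no filter and 12 on TPM, and to 0 with an estimated correlation between genes. The 16 include root hair, which had too few tested genes for the test under the main filter. Estimated correlations for nitrogen assimilation (0.00157), DNA replication (0.008) and auxin (0.00988) were under the preset 0.01. Their unadjusted camera p still rose, from 1.04e-05 to 0.00354, 3.52e-05 to 0.0058 and 0.0129 to 0.0474. A higher correlation between genes therefore does not account for the loss of these lists. In limma camera an estimated correlation also replaces degrees of freedom based on the number of genes by the fewer residual ones, which raises p. For aquaporins (0.685), green tissue (0.34), clock (0.326) and phytoalexins (0.174) the estimated correlation was above the preset. There both changes raise p and were not separated. The causes of these moves were otherwise not tested. Leaving out a library gave 11810 to 13397 genes in TG1, 12761 to 14114 in TG2, 12942 to 14223 in the mean, 6823 to 7977 between the lines, 9062 to 9949 in both, 6 to 10 lists, and an OsTCP19 change of 2.36 to 2.41. Replicate numbers did not pair the libraries, with 0 of 9 correlations of same-numbered libraries over 0.1 (-0.138 to 0.082), and a replicate block gave 12994, 13893, 14252, 7888 and 10101 genes and 7 lists.

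Which direction held the majority depended on scaling. The share higher between the lines was 53.3% as deposited, 63.5% on TPM and 44.4% with median-of-ratios, in TG1 46.2% became 50.8% with quantile normalization, in TG2 51.1% became 48.4% with median-of-ratios, 55.8% on TPM and 55% with quantile normalization, in both lines 47.7% became 50.3% on TPM and 52.8% with quantile normalization, and in the mean 48.6% became 51% on TPM and 52.9% with quantile normalization. Scaling shifted the median of all genes by at most 0.031 and reversed 0 called list genes in limma, of which 149 passed in the mean.

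For lists, what turned was the direction of the camera test, and the value given with it is the list median, which need not change sign. Between the lines, for example, the nitrate (0.047) and clock (-0.026) medians given for ranks are those of the main fit. Directions that reversed belonged to results not past the threshold, apart from the iron list in TG1, whose test turned down under the stricter filter (median 0.084, adjusted p = 0.647, range 0.014 to 0.647). In the mean, that filter also turned gibberellin (-0.005) and iron (-0.094), and iron turned without the run genes (-0.058) and without TG1 replicate 1, 2 or 3 (-0.087 to 0.064 over all left-out libraries). Between the lines, the stricter filter turned auxin (0.033) and gibberellin (0.045), ranks nitrate (0.047) and clock (-0.026), median-of-ratios clock (-0.053), array weights auxin (-0.005) and quantile normalization gibberellin (0.001). Left-out libraries gave -0.051 to -0.004 for clock, turned by TG1 and TG2 replicates 3, -0.019 to 0.034 for auxin, turned by TG1 and TG2 replicates 1, and -0.056 to 0.001 for gibberellin, turned by each wild-type replicate. Among genes in the mean, AOS1 turned on TPM (0.003) and quantile normalization (0.002), WOX11 on the latter (0.013), and EUI1 on TPM (0.012), quantile normalization (0.009) and array weights (0.008). Left-out libraries gave -0.002 to 0.021 for the NPF8.9 locus (turned by TG2 replicate 1), -0.084 to 0.015 for AOS2 (wild-type replicate 2), -0.038 to 0.008 for AOS1 (TG2 replicate 3) and -0.075 to 0.031 for EUI1 (5 libraries). The LBD37 locus in TG2 turned on TPM (0.011). The cause was not tested for these. Calls in the mean ended without wild-type replicate 3 for D3 (adjusted p = 0.0872, range 0.00988 to 0.0872) and without wild-type replicate 1 or 2 for MAS (0.0686 and 0.132, range 4.4e-04 to 0.132), and under 5 or 6 of the left-out libraries for GDH2, BRI1, PRR73, RR4 and the DMAS1 locus, and between the lines for 20 of 110 named genes. Between the lines the ammonium list passed with no filter (adjusted p = 0.0288), the stricter filter (0.0285) and without TG2 replicate 1 (0.0418, range 0.0285 to 0.404), and phytoalexins with no filter (0.0499, range 0.0499 to 0.404). Depth is unknown, so what it limits could not be assessed.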

Other observations

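The splits of the libraries were planned tests, while the single loci without symbols, the chromosome 4 stretch and the choice of values were tests chosen after the result was seen. Phosphate transport genes moved apart: PT1 (LOC_Os03g05620), a phosphate transporter, rose from 84.3 ± 1.39 to 108 ± 1.13 in TG1 and 148.0 ± 7.75 FPKM in TG2, while PT2 (LOC_Os03g05640) fell from 29.6 ± 0.142 to 14.7 ± 0.162 and 17.98 ± 0.944, and PT8 (LOC_Os10g30790) from 57.5 ± 0.825 to 32.3 ± 1.34 and 45.0 ± 3.70. LSI1 (LOC_Os02g51110), a silicon influx channel of the root, was among the most abundant list genes and fell from 1319 ± 6.08 to 1189 ± 23.3 and 979.8 ± 46.9 FPKM. In the hypoxia list, alcohol dehydrogenase genes went opposite ways: ADH1 (LOC_Os11g10480) rose from 8.21 ± 0.577 to 10.4 ± 0.366 and 10.7 ± 0.205 FPKM, and ADH2 (LOC_Os11g10510) fell from 141 ± 2.55 to 105 ± 2.07 and 94.7 ± 1.23.

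Loci without a symbol also changed strongly in both lines, and some that rose and some that fell are given as examples. LOC_Os03g02470 averaged 0.0167 FPKM in wild type, 376.7 in TG1 and 32.3 in TG2, and LOC_Os04g42095 averaged 0.06, 52.9 and 34.5. LOC_Os07g48460 fell from 151 to 13.7 and 14.9 FPKM, and LOC_Os01g29804 from 91.2 to 10.6 and 10.3. Loci near 2 of these in locus order moved the same way. LOC_Os03g02460 went from 2.93 to 92.1 and 11.45 FPKM, and LOC_Os01g29820 from 132 to 20.4 and 24.95. The largest falls in the mean of both lines ended at or near 0. LOC_Os10g22050 went from 17.68 FPKM to 0 and 0.13, and LOC_Os12g38420 (12.52 in wild type) and LOC_Os03g28389 (9.44) went to 0 in both lines. A stretch of chromosome 4 was higher in both lines, with best window medians of 0.54 in TG1 and 0.61 in TG2. Further windows between the lines lay on chromosomes 1 (0.27), 6 (0.28) and 11 (0.25 and 0.31).

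For TG1 against wild type 1 of the 10 splits of the 6 libraries, the real one, gave as many genes (13200, and 0 for the highest of the others), and for TG2 1 of 10 (14148, and 0); splits of 3 against 3 are too few for a share under 0.05. For the mean of both lines 1 of 100 splits of the 9 libraries gave as many genes (14477, with 3434 for the highest of the others). For genes changed the same way in both lines it was also 1 of 100 (10288, with 1518). In both cases this was the real grouping, and 1 of 100 is the lowest share these splits can give. Mixed splits also put the differences between genotypes into the spread within groups, which lowers their counts. A batch shared by the libraries of a genotype is not excluded by these splits. For the 7 lists in the mean 5 of 100 splits gave as many, the highest of the others 9, so that chance cannot be excluded for their number.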
